A study of Homo sapiens with 133 samples.

How the data were processed

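Gene expression was measured by RNA sequencing in 133 libraries of A375, an established human melanoma cell line, after 3 days in 2 µM PLX-4720, an inhibitor of the BRAF kinase. In most libraries a CRISPR activation system had been directed by a guide RNA to 1 of 11 candidate long noncoding RNA loci, with 3 guides per locus, or by 1 of 2 non-targeting guides (NT) to no locus. In the others a MOB3B or a GFP coding sequence was overexpressed. Each locus has 9 libraries, 3 per guide, except TCONS_00026344 with 7; each set of NT libraries has 6, and MOB3B and GFP have 3 each. Per the labels' molecule field, 66 libraries were made from polyA RNA (6 loci, MOB3B, GFP and 6 NT libraries) and 67 from total RNA (5 loci and 24 NT libraries). The protocol text speaks of 6 loci prepared from total RNA depleted of ribosomal RNA, so the 2 sources differ by 1 locus. In TCONS_00010506, labelled total RNA, the transcript TCONS_00022986 holds 0.125% of the TPM (0.241% in its NT libraries), against 33.3 to 38.3% at the other 4 total RNA loci.

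The deposited values are TPM: per the submitters' processing notes the authors used Bowtie 0.12.7, RSEM 1.2.22 and the hg19 genome, without stating the role of each, and every deposited column has the same total. The 12 deposited tables, 1 per locus and 1 for MOB3B, hold 51771 to 52119 entries each, of which 21536 carry TCONS transcript identifiers, 6489 to 6672 carry RefSeq NR and 920 to 1091 RefSeq NM accessions, and the rest carry gene symbols. Accessions were paired with symbols through the GRCh38.p14 gene table; 6836 to 7255 per table matched. That table was used only for names and for which genes neighbour each other, and no coordinates are given because the files use hg19. TCONS identifiers are paired with no name or position in the files or the reference, so no neighbours were looked up for those 6 loci. Per file, 25 symbols had been turned into dates and are named nowhere. All 169 columns were used and 0 were left out. TPM keeps no read depth, so the depth per library is unknown, and no counting intervals are given; the number of entries at 1 TPM or more per library is given instead.

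Each table was analysed alone, with the NT libraries it holds. NT libraries are shared: the 6 polyA loci use 1 set, TCONS_00015940 and TCONS_00011252 use another, NR_034078 and TCONS_00010506 each have their own, and the set in the TCONS_00026344 table nearly repeats that of TCONS_00015940 library by library. The median absolute difference on the log2 scale between the paired NT libraries was 0.0626 to 0.069 in 6 pairs, against 0.0749 to 0.101 between replicates of 1 guide within either set, so these 2 sets were treated as shared. Genes at 1 TPM or more in at least 3 libraries of a table were tested with limma 3.58.1 in R 4.3.3 (limma-trend on log2(TPM + 1)), with the guide as a random block for the loci and no block for MOB3B, and Benjamini-Hochberg adjustment. A gene is called changed at an adjusted p under 0.05. Replicates of 1 guide are not independent tests of a locus, so a fit on guide means (3 against 2) was run beside each, and each guide was also set against NT alone. Both used deposited values. The p-values measure the spread between libraries: the labels do not say whether replicates were separate cultures.

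Values were also rescaled per library by the median of its ratios to the geometric mean over libraries. Where the median change of all genes is more than 0.1 log2 away from 0, in 4 tables, gene and list results are given on the rescaled values. Genes called at many loci, genes called both at a locus and for MOB3B, and correlations between loci use rescaled values in every table, and correlations with MOB3B use deposited values. A set of 21 gene lists was written beforehand: genes of 9p21.2, targets of YAP and TAZ, Hippo pathway members, MAPK output genes, MITF and melanocyte genes, dedifferentiation and resistance genes, E2F and G2/M genes, p53 targets, type I interferon genes, NF-κB inflammatory genes, stress response genes, cholesterol synthesis, hypoxia and glycolysis, matrix and EMT genes, ribosomal proteins, nuclear oxidative phosphorylation genes, replication-dependent histones, and markers of epithelial cells, leukocytes, fibroblasts and endothelium, and HEK293 cells. Each was tested with cameraPR on the moderated statistics, with a preset inter-gene correlation of 0.01 and adjustment over the 21 lists of a comparison. The same lists were tested by camera with an estimated correlation, which asks the same question of a list against all other genes, and by fry. Its directional p asks whether a list's genes move on balance one way and its mixed p whether they change in either direction, and neither compares the list with other genes. Where a list has its own count "adjusted over the list alone", the adjustment covers its members only. List counts cover only members past the filter. For MOB3B these were 6 of 14 epithelial markers, 12 of 25 melanocyte genes and 4 of 14 leukocyte markers.

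The genes named in the text follow a rule. Named are the target, its neighbours (5 on each side where the target can be placed) and EQTN, MOB3B, IFNK and C9orf72. Named also are up to 10 risers and 10 fallers per comparison, the largest among called genes whose every guide mean lies on one side of both NT guide means (for MOB3B, whose 3 libraries lie on one side of the 3 GFP libraries) and whose higher group averages at least 5 TPM. From each list that passed or had a called member, up to 4 genes with the smallest p are added. The text leaves out some of these. Several named genes have near-identical relatives that RSEM may have divided reads between, such as CGB5 and CGB8, HLA-DQA1 and HLA-DQA2, and SULT1A3 and SULT1A4, and their values are uncertain for that reason.

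Correlations between loci that share NT libraries were compared with those of unchanged groups simulated against the same libraries (20 simulations per pair) and with fits that gave NT guide 1 to one locus and NT guide 2 to the other. The fit was tested on simulated data, with 100 genes per comparison changed by 1.5-fold and 100 by 3-fold, raised and lowered in equal numbers. It recovered 41 to 84% of the former and 84 to 96% of the latter, and called 5 unchanged genes for MOB3B and 70 to 230 per locus. Unchanged genes were 5 of 169 calls for MOB3B. At the loci their share ran from 82 of 258 calls at NR_034078 to 230 of 379 at TCONS_00010506. In these simulations the locus fit therefore did not hold its error rate at the threshold used. Adjusted p-values and counts of changed genes at the loci are lenient for that reason. Guide means called at most 10 unchanged genes and recovered 2 to 63 of the 100 smaller and 55 to 90 of the 100 larger changes. In a separate test 12 of 12 raised lists passed and 0 unchanged lists did. The raised lists held only genes raised 3-fold, and genes were simulated without correlation between them. That test therefore does not cover lists of correlated genes.

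The design, the 21 lists, the naming rule and the alternative settings below were fixed before the data were examined. They were a pseudocount of 0.1, no filter and a filter at 5 TPM, rescaling, no guide block, guide means, the replicate number as a block, a log2 limit of 0.5, leaving out each library and each guide, an estimated correlation and fry for lists, and, for the similarity to MOB3B, a mean of at least 5 TPM, Spearman's coefficient and rescaling. Further alternatives chosen after seeing the data left out 2 libraries of NR_109890 and 3 of TCONS_00026344, split the shared controls, and took each TCONS_00015940 guide alone. Alternatives meant for read counts did not apply, since the values are TPM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.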

Results

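RNA sequencing of 133 A375 melanoma libraries measured what changed when 1 of 11 candidate long noncoding RNA loci was activated with CRISPR, or when MOB3B was overexpressed, in cells kept for 3 days in 2 µM PLX-4720, a BRAF inhibitor. Each library held 13241 to 18815 genes at 1 TPM or more. Each correlated across genes with the other libraries of its table, controls included, at a mean r of 0.932 to 0.984. Changes are log2 fold changes against the non-targeting (NT) or GFP libraries of the same table, each with its standard error (SE) and the adjusted p of limma, and levels are mean TPM ± SD. Every gene named for the size of its rise or fall had each guide mean on one side of both NT guide means. The p-values measure the spread between libraries, and the labels do not say that replicates were separate cultures. On simulated data the locus fit called more unchanged genes than its threshold allows, so adjusted p-values and counts at the loci are lenient. Unless stated, each locus has 9 libraries against 6 NT libraries, and MOB3B has 3 against 3 GFP libraries.

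MOB3B, a member of the MOB family of kinase regulators, reached 325 ± 5.07 TPM against 0.667 ± 0.289 in GFP libraries (log2 7.63, SE 0.11, adjusted p = 1.3e-06, n = 3 and 3). NPPB, the precursor of a natriuretic peptide, rose by 2.46 (SE 0.26, adjusted p = 9.2e-04) and COL1A1, a chain of type I collagen, by 2.14 (SE 0.06, 1.5e-05). TAGLN, an actin-binding protein, rose by 1.33 (SE 0.04, 2.0e-05) and GDF15, a stress-induced cytokine and p53 target, by 1.48 (SE 0.07, 6.3e-05). FGF1, a growth factor, fell by 1.12 (SE 0.05, 3.2e-05). TGFBR2, a TGF-β receptor, fell by 0.69 (SE 0.03, 3.6e-05), and EDNRB, the endothelin receptor of melanocytes, by 0.77 (SE 0.05, 1.5e-04).

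Of 25 type I interferon genes 23 fell under MOB3B and 0 rose (24 fell when adjusted over the list alone), with a median of −0.79 and an adjusted p of 4.4e-06 for the list, against an adjusted p = 0.28 with an estimated correlation. IFIT1 fell by 1.56 (SE 0.20, 0.0018) and IFIT3 by 0.91 (SE 0.13, 0.0024), both induced by interferon. All 6 epithelial markers tested, of 14 listed, rose (median 0.82, adjusted p = 1.1e-14, and 0.13 with an estimated correlation), among them the keratins KRT8 (1.13, SE 0.08, 1.9e-04) and KRT18 (0.73, SE 0.03, 3.4e-05). Of 12 melanocyte genes 7 fell and 1 rose (adjusted p = 6.9e-05; adjusted p = 0.23 with an estimated correlation), including DCT, an enzyme of melanin synthesis (−0.61, SE 0.06, 6.7e-04). Of 23 MAPK output genes 11 fell and 3 rose (adjusted p = 0.016; adjusted p = 0.23 with an estimated correlation), including DUSP4, a phosphatase of the pathway (−0.54, SE 0.03, 1.5e-04). Of 14 NF-κB inflammatory genes 11 fell and 1 rose (adjusted p = 0.0012; adjusted p = 0.13 with an estimated correlation), including the chemokines CCL2 (−0.97, SE 0.08, 3.8e-04) and CXCL1 (−0.82, SE 0.07, 3.8e-04). Of 29 E2F and G2/M genes 18 rose and 0 fell (adjusted p = 1.6e-07; adjusted p = 0.23 with an estimated correlation), including CDC20, an activator of the anaphase-promoting complex (0.58, SE 0.04, 1.4e-04).

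Among genes of the Hippo pathway under MOB3B, WWTR1, which encodes TAZ, fell by 0.69 (SE 0.04, 8.2e-05), VGLL4, a TEAD cofactor, by 0.56 (SE 0.03, 1.3e-04) and TEAD1 by 0.42 (SE 0.06, 0.0024). Of the 24 members 9 fell and 4 rose, 12 and 4 when adjusted over the list alone, with a median of −0.16, a mean of 0.16 that MOB3B itself raises, and an adjusted p of 0.46. Of 28 YAP and TAZ targets 11 rose and 5 fell, 12 and 5 when adjusted over the list alone (adjusted p = 0.09): CYR61 rose by 0.29 (SE 0.04, 0.0022) and IGFBP3 fell by 0.64 (SE 0.06, 5.1e-04). Of 23 dedifferentiation genes 10 rose and 9 fell (median 0.11; tested downward, adjusted p = 0.88), of 28 matrix and EMT genes 7 rose and 13 fell, 8 and 14 when adjusted over the list alone (median −0.12, mean 0.00323, tested downward, adjusted p = 0.53), and of 4 leukocyte genes 1 rose and 2 fell (adjusted p = 0.16).

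Metabolic lists rose under MOB3B: 11 of 23 cholesterol synthesis genes rose and 2 fell (adjusted p = 2.2e-04), 12 of 26 oxidative phosphorylation genes rose and 1 fell, 13 and 1 when adjusted over the list alone (1.8e-04), and 10 of 20 hypoxia and glycolysis genes rose and 4 fell, 11 and 4 when adjusted over the list alone (0.0084). For each of these 3 lists the adjusted p was 0.13 with an estimated correlation. The stress response list also passed upward by cameraPR (10 of 22 up, 7 down, adjusted p = 0.017). So did p53 targets (8 of 20 up, 4 down, 0.0012) and fibroblast and endothelial markers (2 of 5 up, 0 down, 1.8e-04). HEK293 markers passed too (2 of 5 up, 0 down, 0.029). Each of these lists had an adjusted p = 0.23 with an estimated correlation. The ribosomal protein list passed upward by cameraPR with 11 of 30 genes up and 5 down (adjusted p = 0.024). Its adjusted p was 0.25 with an estimated correlation. Replication-dependent histones fell (8 of 13 down, 1 up, 9 and 2 when adjusted over the list alone, adjusted p = 0.0012, and 0.23 with an estimated correlation). Only 13 of the 19 listed histones passed the filter in these polyA libraries. Of the 6 genes of 9p21.2 tested 1 rose, MOB3B, and 1 fell, 1 and 3 when adjusted over the list alone. The list's median (−0.17), mean (1.11) and upward test (adjusted p = 2.8e-07; adjusted p = 0.97 with an estimated correlation) differ in sign because of MOB3B.

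MOB3B overexpression changed 6142 of 16257 genes, 2124 higher and 4018 lower, 1126 of them by at least 0.5 on the log2 scale. On rescaled values 5595 changed, 2667 higher and 2928 lower, and without MOB3B replicate 2 the count was 3989.

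Activation of TCONS_00015940 raised the targeted transcript and genes of 9p21.2 with guide 2. There the transcript reached 13.5 ± 1.16 TPM against 0.0267 ± 0.0137 in NT, MOB3B 81.2 ± 2.88 against 0.168 ± 0.0402, and IFNK, which encodes interferon kappa, 116 ± 12.7 against 0 in all 6 NT libraries. With guide 1 the transcript was at 0.07 ± 0.0436 and MOB3B at 0.593 ± 0.0404 TPM, with guide 3 at 0.167 ± 0.0513 and 2.28 ± 0.125 TPM. The MOB3B mean of each guide lay above the highest NT library (0.21 TPM). IFNK was at 0.0333 ± 0.0289 and 0.0167 ± 0.0289 TPM with guides 1 and 3, and EQTN, a sperm acrosome gene, at 0.137 ± 0.131 TPM with guide 2 and 0 elsewhere. The guides differed in limma for the transcript (adjusted p = 9.3e-12), MOB3B (1.2e-15) and IFNK (2.1e-15).

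**Figure D1:**
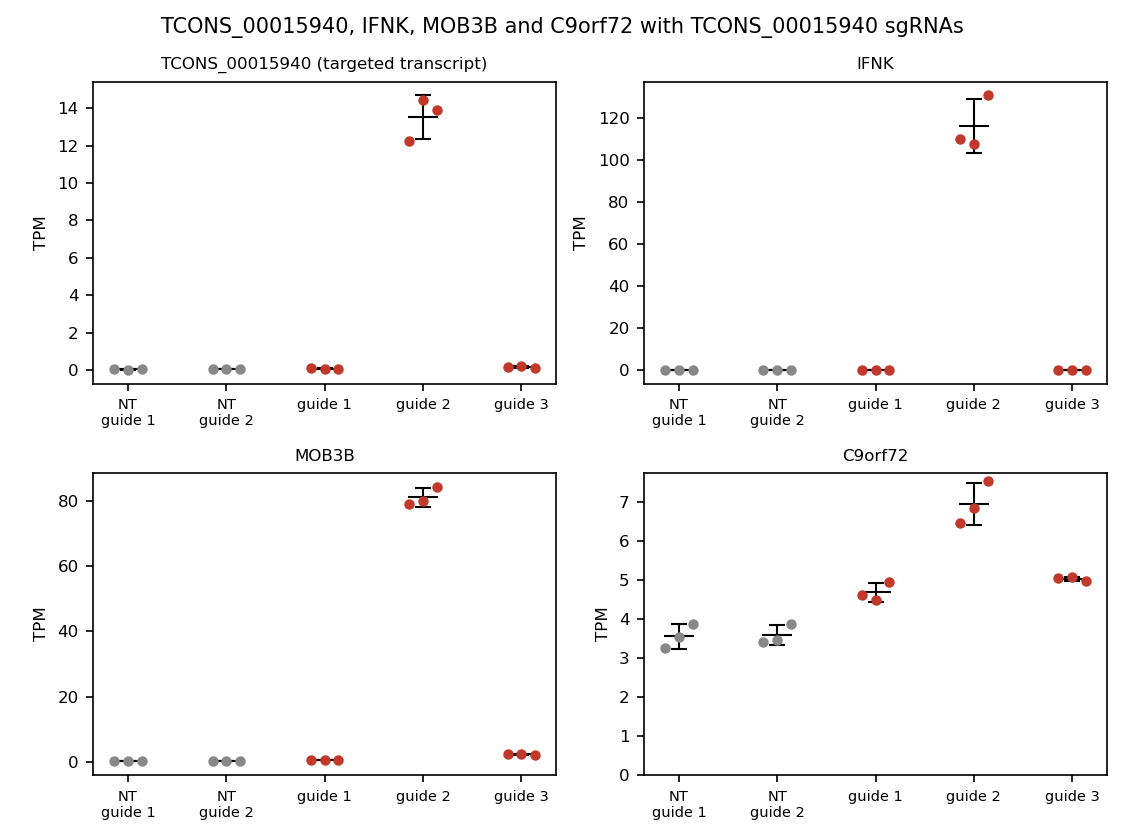
TPM of TCONS_00015940, IFNK, MOB3B and C9orf72 by NT guide and TCONS_00015940 guide, 1 point per library, with mean and SD. MOB3B means are 0.593, 81.2 and 2.28 TPM with guides 1 to 3, and IFNK reaches 116 TPM with guide 2.

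Over the 3 guides the rise of MOB3B was 2.69 (SE 0.99, adjusted p = 0.027) on the deposited values and 2.54 (SE 0.97, adjusted p = 0.062) on the rescaled values. That of the transcript was 1.35 (SE 0.70, adjusted p = 0.11) and 1.28 (SE 0.68, 0.18), and that of IFNK 2.31 (SE 1.29, 0.13) and 2.25 (SE 1.26, 0.21). C9orf72, a gene of membrane traffic, was 0.51 higher (SE 0.11, adjusted p = 9.5e-04) and 0.18 higher after rescaling (SE 0.10, 0.21), with 4.68, 6.94 and 5.02 TPM by guide against 3.56 in NT. IFT74, PLAA and CAAP1 differed by 0.10 (SE 0.07, 0.31), −0.06 (SE 0.04, 0.34) and −0.09 (SE 0.06, 0.33) after rescaling. In this table the median of all genes was 0.32 higher than in NT, so its other changes are given on rescaled values.

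On that scale, HLA-DRA, a class II antigen presentation molecule, fell at TCONS_00015940 by 1.87 (SE 0.14, adjusted p = 5.1e-07) and CD74, the invariant chain, by 1.51 (SE 0.09, 1.0e-07). FDCSP, a secreted peptide, fell by 2.88 (SE 0.22, 6.0e-07). The chemokine CCL2 fell by 1.42 (SE 0.16, 1.4e-05) and SPRY2, a feedback inhibitor of the MAPK pathway, by 0.88 (SE 0.07, 7.8e-07). MKI67, a proliferation marker, rose by 1.32 (SE 0.14, 1.1e-05) and KRT8 by 1.08 (SE 0.10, 3.2e-06). AJUBA, a YAP target, rose by 0.79 (SE 0.15, 0.0014) and COL5A1, a collagen, by 0.64 (SE 0.08, 2.6e-05). Of 30 ribosomal protein genes 29 fell and 0 rose, 30 and 0 when adjusted over the list alone (adjusted p = 6.2e-19; adjusted p = 0.21 with an estimated correlation). On the deposited values the list did not pass (adjusted p = 0.913). Of 14 NF-κB genes 9 fell and 1 rose, 10 and 1 when adjusted over the list alone (2.2e-06; adjusted p = 0.082 with an estimated correlation). Of 26 interferon genes 1 rose and 0 fell, 0 and 0 when adjusted over the list alone, with a median of 0.98 and an adjusted p of 0.021 for the list (adjusted p = 0.66 with an estimated correlation), and that gene, IFI44, was at 45.9 ± 34.4 against 12.6 ± 1.72 TPM (1.09, SE 0.38, 0.041). These values pool the 3 guides, although IFNK was high with guide 2 only. They do not show how far the interferon genes differ between guides.

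At TCONS_00015940 9668 of 15650 genes changed, 9397 higher and 271 lower, and 8240 on guide means, 8049 higher and 191 lower. Those guide means are of deposited values, which hold the shift of the median in this table. On rescaled values 4564 changed, 1951 higher and 2613 lower, and 2221 genes were called in both with one sign and 794 with opposite signs. Without NT guide 1 the count on deposited values was 6420.

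At NR_109890 (LINC02202 in GRCh38.p14) the target rose to 6.36 ± 3.40 TPM against 0.503 ± 0.149 in NT (log2 2.14, SE 0.29, adjusted p = 4.2e-04), and its neighbour EBF1, a transcription factor of B cell and adipocyte development, to 17.5, 56.3 and 21.3 TPM by guide against 0.678 ± 0.111 TPM (4.08, SE 0.30, 2.3e-06). By guide the target was at 6.87, 9.74 and 2.46 TPM. TEK, an endothelial receptor tyrosine kinase encoded at 9p21.2, rose by 1.47 (SE 0.25, 0.0021), GJA5, a gap junction protein, by 2.90 (SE 0.57, 0.0067). COL17A1 rose by 1.92 (SE 0.20, 3.9e-05) and ADAMTS2, a procollagen protease, by 1.82 (SE 0.27, 7.1e-04). LCN2, an iron-sequestering innate immune protein, fell by 2.77 (SE 0.20, 2.3e-06, 1.03 ± 0.609 against 12.5 ± 1.72 TPM), and the chemokine CXCL8 by 1.73 (SE 0.14, 6.8e-06). Falls were also seen in the complement gene C3 by 1.40 (SE 0.25, 0.0034) and NFKBIA, the inhibitor of NF-κB, by 0.66 (SE 0.06, 1.1e-05). Of 18 NF-κB genes 17 fell and 0 rose, 18 and 0 when adjusted over the list alone (adjusted p = 7.9e-49; 0.035 with an estimated correlation). The count of changed genes was 959 of 18969 (419 higher, 540 lower). It was 1386 after rescaling (660 higher, 726 lower), 0 on guide means in limma (2097 at an unadjusted p under 0.05), 2018 without guide 2 replicate 3 and guide 3 replicate 1, whose libraries stand apart, 3298 without guide 2 replicate 3 alone, 2721 without guide 2, 130 without NT guide 1 and 148 without NT guide 2.

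At NR_034078 (a transcript of CASP4LP in GRCh38.p14) the named transcript was at 0.00222 ± 0.00667 TPM, and the other CASP4LP transcript, NR_034079, at 14.2 ± 12.2 against 0.0117 ± 0.0286 TPM in NT (rescaled 2.89, SE 0.83, adjusted p = 0.044), with 18.1, 24.3 and 0.0533 TPM by guide. Its neighbour CASP4, an inflammatory caspase, was at 25.3 ± 2.90 and 23.1 ± 0.916 TPM (rescaled −0.01, SE 0.05, adjusted p = 0.97). DKK1, a secreted WNT antagonist, rose by 0.68 (SE 0.08, 1.3e-04, 101 ± 8.35 against 58.0 ± 8.96 TPM) and KRT8 by 0.66 (SE 0.06, 3.2e-05). UBD, a ubiquitin-like modifier, fell by 1.16 (SE 0.08, 1.5e-06), CCL2 by 1.00 (SE 0.09, 2.9e-05) and PHLDA1 by 0.54 (SE 0.05, 3.2e-05). On rescaled values 19 of 29 E2F and G2/M genes rose and 0 fell, 24 and 0 when adjusted over the list alone (adjusted p = 3.0e-21; adjusted p = 0.068 with an estimated correlation), and 8 of 14 NF-κB genes fell and 0 rose, 11 and 0 when adjusted over the list alone (4.0e-16; 0.013 with an estimated correlation). The median of all genes was 0.10 higher than in NT. Of 15133 genes 2471 changed (2347 higher, 124 lower), 1199 after rescaling (684 higher, 515 lower) and 3 on guide means. At an unadjusted p under 0.05 in limma, 3521 differed on guide means, 3238 higher and 283 lower. Those guide means are of deposited values, which hold the shift of the median. The count of 2471 became 1510 without NT guide 1 replicate 1, 148 without NT guide 1 and 1151 without NT guide 2.

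**Figure D2:**
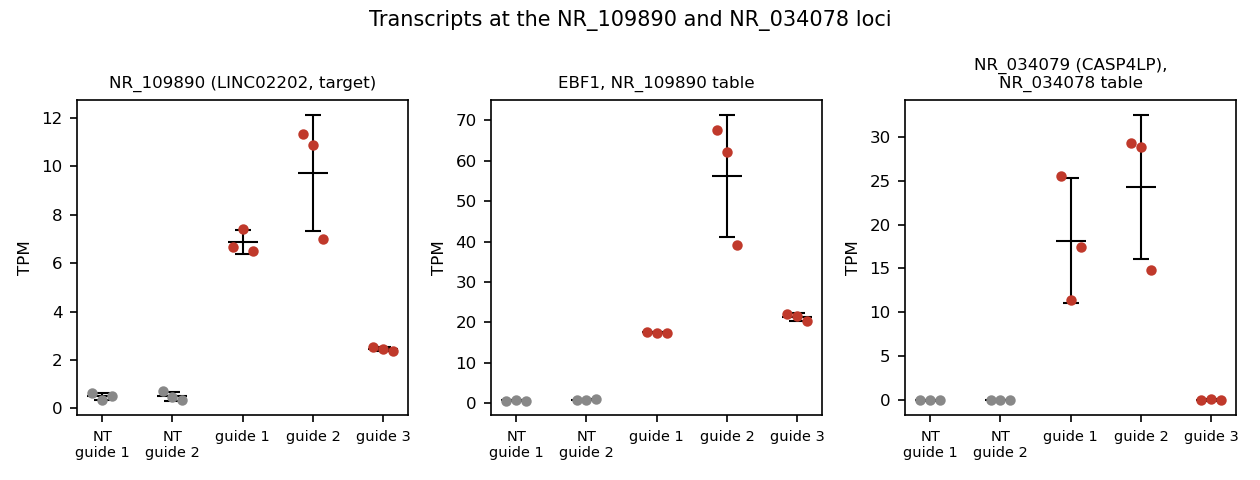
TPM of LINC02202 and EBF1 at NR_109890 and of NR_034079 (CASP4LP) at NR_034078 by NT guide and locus guide, 1 point per library, with mean and SD. EBF1 means are 17.5, 56.3 and 21.3 TPM with guides 1 to 3, and NR_034079 is at 0.0533 TPM with guide 3.

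At 8 other loci the target stayed under 1 TPM on average. It was listed at 0 in every activated library for TCONS_00011252, NR_033834 (FZD10-AS1), NR_125939, TCONS_00006579 and TCONS_00009861, averaged 0.306 ± 0.446 TPM against 0 for TCONS_00026344 (n = 7 and 6) and 0.428 ± 0.204 against 0.302 ± 0.115 TPM for TCONS_00010506, and LINC00174, the target of NR_026873, 0.492 ± 0.264 against 0.497 ± 0.221 TPM. None of these reached the filter for a test. Among their neighbours, ASL, an enzyme of the urea cycle, rose by 0.20 at NR_026873 (SE 0.06, adjusted p = 0.021), and FZD10, a WNT receptor, was at 0.0267, 0.843 and 0.36 TPM by guide at NR_033834 and at 0 in NT.

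At TCONS_00011252 and TCONS_00026344, where the median of all genes was 0.13 and 0.25 higher than in NT, genes are given on rescaled values. At TCONS_00011252 CDC20 rose by 0.61 (SE 0.04, adjusted p = 1.9e-07) and DKK1 by 0.74 (SE 0.07, 3.0e-06). ANKRD1, a YAP target, rose by 0.76 (SE 0.11, 9.7e-05) and the histone HIST1H3B by 0.55 (SE 0.06, 1.8e-05). C3 of the complement system fell by 0.92 (SE 0.10, 1.4e-05), UBD by 1.16 (SE 0.09, 7.5e-07) and WWTR1 by 0.47 (SE 0.06, 4.5e-05). Of its 19 histone genes 18 rose and 1 fell (adjusted p = 4.4e-18; adjusted p = 0.17 with an estimated correlation), and of 28 YAP and TAZ targets 16 rose and 1 fell (5.8e-10; 0.040 with an estimated correlation). At TCONS_00026344 PDE2A, a phosphodiesterase, rose by 2.43 (SE 0.70, 0.015), UPK3B by 1.95 (SE 0.30, 2.7e-04), APOE by 1.38 (SE 0.34, 0.0061), MKI67 by 1.25 (SE 0.12, 9.0e-06) and FOSL1, an AP-1 subunit, by 1.02 (SE 0.18, 6.1e-04). CCL2 fell by 1.91 (SE 0.24, 6.2e-05), HLA-DRA by 1.05 (SE 0.12, 3.5e-05) and DUSP4 by 0.78 (SE 0.06, 2.7e-06).

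Counts at TCONS_00011252 were 5554 of 14664 genes (5154 higher, 400 lower), 3605 after rescaling (1967 higher, 1638 lower), 3778 on guide means and 3395 without NT guide 1. Those at TCONS_00026344 were 9476 of 15016 (9081 higher, 395 lower), 5273 after rescaling (2368 higher, 2905 lower) and 8010 on guide means, with 702 genes called on both scales with opposite signs. The counts on guide means, and that without NT guide 1, are of deposited values, which hold the shift of the median. In this table IFNK reached 1.2 TPM in 1 library and was above every NT library in 3, and without those 3 the count was 8961.

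At TCONS_00010506 ANKRD1 rose by 1.80 (SE 0.36, adjusted p = 0.0016, 63.9 ± 46.4 against 14.2 ± 0.533 TPM) and NPPB by 1.75 (SE 0.20, 1.8e-05). KISS1, the kisspeptin precursor, rose by 1.59 (SE 0.30, 0.0010), AURKA, a mitotic kinase, by 0.90 (SE 0.07, 2.3e-06) and CYR61, a matricellular YAP target, by 0.81 (SE 0.08, 4.1e-06). C3 fell by 2.32 (SE 0.22, 4.8e-06, 34.9 ± 14.2 against 168 ± 29.2 TPM), MGP, an inhibitor of calcification, by 1.83 (SE 0.18, 5.4e-06), CD74 by 1.12 (SE 0.24, 0.0025) and MMP2, a matrix protease, by 0.96 (SE 0.13, 5.3e-05). Of 28 YAP and TAZ targets 14 rose and 0 fell, 15 and 1 when adjusted over the list alone (adjusted p = 3.9e-07; adjusted p = 0.17 with an estimated correlation), and of 28 matrix and EMT genes 16 fell and 3 rose, 17 and 3 when adjusted over the list alone (3.0e-05; adjusted p = 0.34 with an estimated correlation). MOB3B was at 0.747, 1.75 and 0.947 TPM by guide against 0.628 in NT (0.37, SE 0.16, adjusted p = 0.11). Of 20808 genes 5122 changed (2380 higher, 2742 lower), 1062 on guide means, 3276 without NT guide 1 and 2361 without NT guide 2; on rescaled values 2930 were higher and 2259 lower.

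At NR_026873 and NR_033834 TK1, thymidine kinase, rose by 1.02 (SE 0.09, adjusted p = 1.5e-06, 169 ± 21.7 against 82.3 ± 8.56 TPM) and 0.93 (SE 0.09, 2.3e-05), SPC24, a kinetochore protein, by 1.07 (SE 0.10, 1.3e-06) and 1.01 (SE 0.13, 1.5e-04), and CNN1, a smooth muscle calponin, by 1.24 (SE 0.12, 2.7e-06) and 1.79 (SE 0.30, 0.0010). At NR_026873 RRM2 rose by 0.94 (SE 0.07, 2.8e-07), MCM5 by 0.87 (SE 0.06, 3.1e-07) and all 29 E2F and G2/M genes rose (4.9e-77; 0.027 with an estimated correlation). At NR_033834 24 of 29 rose and 0 fell, 26 and 0 when adjusted over the list alone (9.4e-33; adjusted p = 0.33 with an estimated correlation). At NR_026873 12 of 20 p53 targets fell and 0 rose, 13 and 0 when adjusted over the list alone (8.6e-07; 0.028 with an estimated correlation), CDKN1A among them (−0.40, SE 0.04, 1.1e-06). C3 fell to 211 ± 46.0 TPM at NR_026873 (−1.44, SE 0.13, 1.0e-06) and 198 ± 64.4 at NR_033834 (−1.56, SE 0.18, 8.1e-05) from 561 ± 30.0 in the NT libraries that the 6 polyA loci share. At NR_033834 CXCL8 fell by 2.03 (SE 0.23, 6.2e-05) and CXCL1 by 1.63 (SE 0.12, 3.8e-06). At NR_026873 3916 of 18483 genes changed (1736 higher, 2180 lower; 2063 and 1830 after rescaling), 1410 on guide means and 1853 without NT guide 2. At NR_033834 2362 of 18879 changed (1036 higher, 1326 lower; 1455 and 1450 after rescaling), 7 on guide means (3267 at an unadjusted p under 0.05), 4951 without the guide block, 4180, 1304 and 3735 without guides 1 to 3, and 598 and 404 without NT guides 1 and 2.

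NR_125939, TCONS_00006579 and TCONS_00009861 had rises of E2F and G2/M genes, 28 of 29 (adjusted p = 1.2e-41), 26 (1.0e-30) and 29 (7.3e-61), with 0 lower. With an estimated correlation the adjusted p was 0.11, 0.25 and 0.18. BUB1, a spindle checkpoint kinase, rose by 0.93 at NR_125939 (SE 0.08, 2.5e-06), PIF1, a DNA helicase, by 1.12 at TCONS_00006579 (SE 0.09, 2.5e-06) and BIRC5, which encodes survivin, by 0.84 at TCONS_00009861 (SE 0.05, 5.1e-08). C3 fell by 1.65 (SE 0.05, 3.6e-11), 1.39 (SE 0.06, 2.2e-09) and 1.93 (SE 0.21, 6.7e-06) at the 3 loci. KRT8 rose by 0.74 (SE 0.18, 0.0071) at NR_125939 and 1.00 (SE 0.27, 0.017) at TCONS_00006579. CDKN1A fell by 0.48 (SE 0.03, 4.3e-07), 0.48 (SE 0.06, 8.3e-05) and 0.52 (SE 0.04, 4.1e-07). BCYRN1, a noncoding RNA of RNA polymerase III, rose by 1.33 (SE 0.18, 4.0e-05) and BST2, an interferon-induced antiviral protein, fell by 1.56 (SE 0.42, 0.012) at TCONS_00009861. PLAA at 9p21.2 rose by 0.16 there (SE 0.05, 0.024) and by 0.17 at TCONS_00010506 (SE 0.05, 0.013).

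Counts at NR_125939 were 4191 of 18984 genes (2203 higher, 1988 lower; 2023 and 2463 after rescaling), 636 on guide means, 6708 without the guide block, 1646 without NT guide 1 and 1962 without NT guide 2. TCONS_00006579 had 3380 of 19065 (1883 higher, 1497 lower; 1650 and 2129 after rescaling), 243 on guide means, 5797 without the guide block, 1183 without NT guide 1 and 739 without NT guide 2. TCONS_00009861 had 4881 of 18760 (2482 higher, 2399 lower; 2636 and 2713 after rescaling), 1907 on guide means, 2571 without NT guide 1 and 2847 without NT guide 2.

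Across the 11 loci the E2F and G2/M list rose at 11 (medians 0.22 to 0.82) and the NF-κB list fell at 11 (medians −0.81 to −0.28). The 11 loci rest on 4 separate sets of NT libraries, and the 6 polyA loci share 1 set. Every set uses the same 2 NT guides. Counts of loci in this paragraph are therefore not counts of independent results. With an estimated correlation 1 and 4 of these lists passed, the adjusted p reaching 0.59 and 0.48. YAP and TAZ targets rose at 8 loci (1 with an estimated correlation), and p53 targets fell at 8 (2), MAPK output genes at 7 (1), melanocyte genes at 6 (2), matrix and EMT genes at 5 (1) and leukocyte markers at 3 (0). Replication-dependent histones fell at 7 loci and rose at 2 (1 and 0 with an estimated correlation), interferon genes fell at 5 and rose at 1 (0 and 0), and ribosomal protein genes fell at 3 and rose at 1 (0 and 0). At the 4 loci with a shifted median, all labelled total RNA, 19 histones were tested, against 13 to 16 at the others. Whether the RNA preparation bears on the direction of the histones was not tested. Epithelial markers and cholesterol synthesis genes rose at 4 loci each (1 each), oxidative phosphorylation genes rose at 3 and fell at 1 (1 and 0), hypoxia and glycolysis genes rose at 2 (1), stress response genes at 1 (0), and Hippo members fell at 1 (0). The 9p21.2, dedifferentiation, fibroblast and endothelial, and HEK293 lists passed at 0 of the 11 loci by cameraPR, with lowest adjusted p-values of 0.43, 0.077, 0.12 and 0.17.

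**Figure D3:**
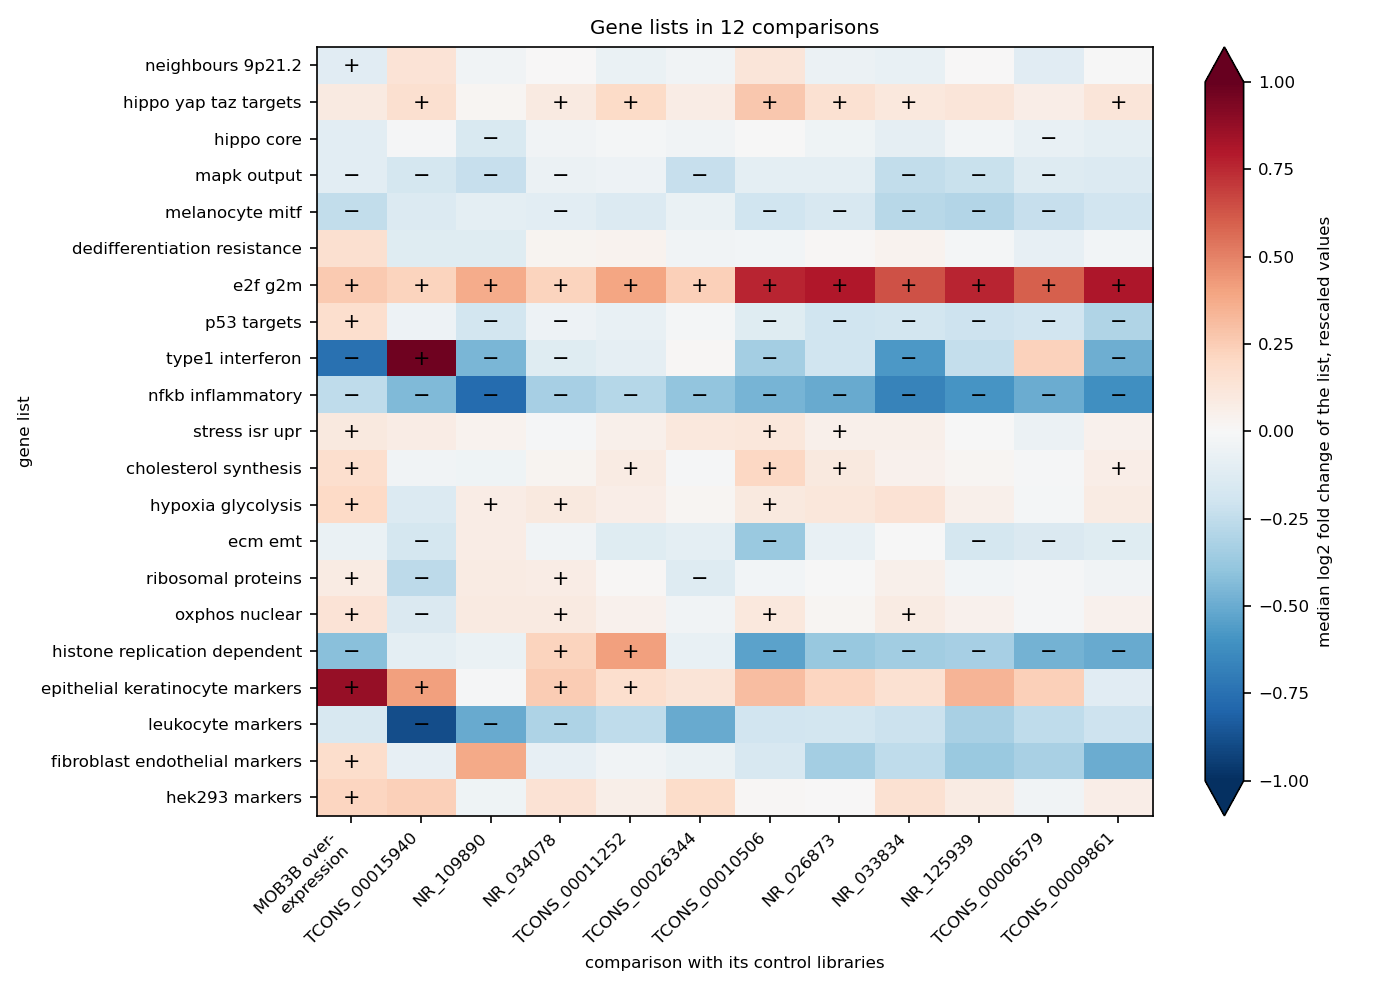
Median log2 fold change, by colour, of each gene list (vertical) in each comparison (horizontal), with + or − where the list passed its test. All comparisons are drawn on rescaled values, so marks can differ from the text, which uses those for 4 loci; the NF-κB list has a − at all 11 loci.

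On rescaled values in every table, MOB3B included, 417 of the 13566 genes tested at every locus were higher and 432 lower in at least 9 of the 11 loci, 55 and 83 of them in all 11. Of the 417 and 432, 255 and 326 changed the same way under MOB3B overexpression, with 1 and 7 changing the opposite way. Independent calls would give 0.00195 and 0.00355 genes, but loci that share NT libraries are not independent. Over 18 sets of 4 loci that share no NT library, a median of 249 of 13332 genes were higher in all 4 (range 72 to 398) and 232.5 lower (135 to 266), where n1 × n2 × n3 × n4 / N³ gives 2.36 and 1.51. These loci still share the 2 NT guides, and any effect of those guides enters all 4. The product assumes independent calls, so the excess does not count independent results.

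Pairs of loci correlated across genes, which are not independent replicates, on rescaled guide means. The 37 pairs with no shared NT library had a median r of 0.395 (0.243 to 0.588) and a covariance of 0.0293 (0.0142 to 0.0511). They still share the 2 NT guides. The 18 pairs with shared NT libraries had 0.714 (0.441 to 0.804) and 0.0579 (0.0241 to 0.075), where groups without any effect, simulated against the same libraries, had 0.611 (0.546 to 0.653) and 0.0286 (0.0141 to 0.0371). With NT guide 1 given to one locus and NT guide 2 to the other, an alternative chosen after seeing the data, the shared pairs had a median r of 0.425 (0.278 to 0.578) and a covariance of 0.0417 (0.0196 to 0.0584).

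**Figure D4:**
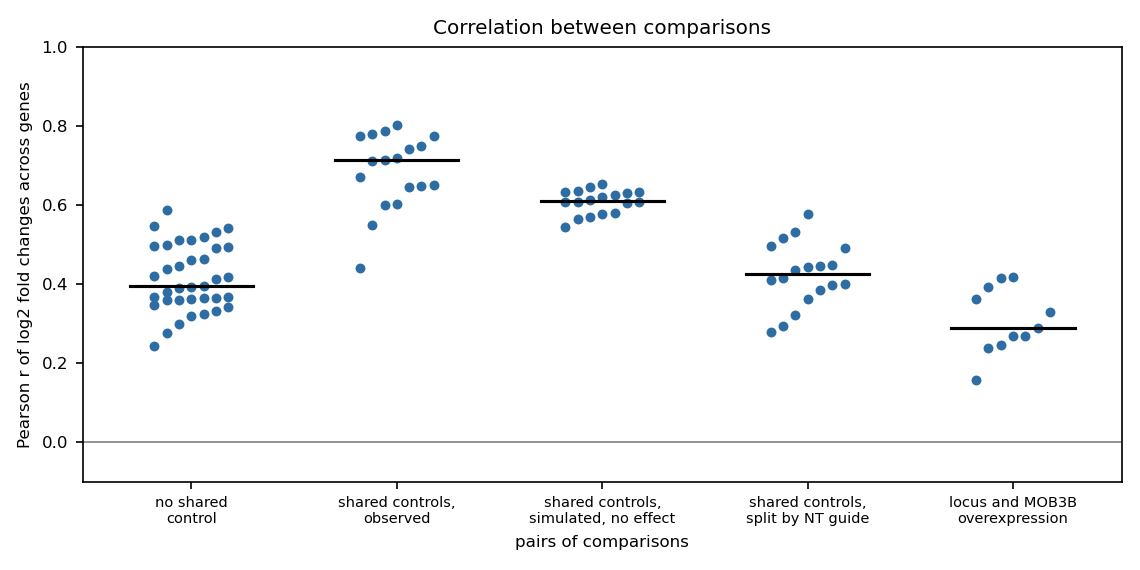
Pearson r across genes of log2 fold changes for pairs of comparisons, 1 point per pair, with a line at the median. Medians are 0.395 for 37 pairs with no shared NT library, 0.714 for 18 pairs with shared ones, 0.611 simulated and 0.425 with split controls, and the last group sets each locus against MOB3B overexpression.

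The changes at each locus also correlated across genes with those of MOB3B overexpression, whose GFP controls are separate libraries. On deposited values the r was 0.417 at TCONS_00011252, 0.414 at NR_033834, 0.391 at TCONS_00006579, 0.363 at NR_026873, 0.329 at TCONS_00010506, 0.288 at TCONS_00026344, 0.269 at TCONS_00015940 and NR_125939, 0.246 at NR_034078, 0.239 at NR_109890 and 0.158 at TCONS_00009861. By calls on rescaled values in both tables, at TCONS_00011252 1076 genes were higher and 1078 lower in both (n1 × n2 / N gives 351 and 308) and 83 opposite (662), and at TCONS_00015940 589 and 1105 (337 and 478) and 433 opposite (808). By guide, r at TCONS_00015940 was 0.292, 0.230 and 0.183, and guide 2, with the MOB3B level of 81.2 TPM, did not have the highest. The SD of r over the guides was 0.0544. Guide 2 also raised IFNK, so these values do not isolate the part played by the MOB3B level.

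On deposited values a single guide against both NT guides changed 645 to 11760 genes over the 33 guides. The highest count, at TCONS_00015940 guide 1, had 11336 higher and 424 lower, with the median of all genes 0.34 higher. NT guide 1 against NT guide 2, with fewer libraries, changed 2 to 349 genes over the 11 tables, some of which share NT libraries. These counts do not compare the guides of a locus with one another.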

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

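The tests of the IFNK values at TCONS_00026344 were chosen only after the result was seen. The guides of a locus were compared with limma, with adjustment over all genes. Guides have 3 libraries, or 2 for guides 2 and 3 of TCONS_00026344, so single libraries far from the rest of their guide were not tested.

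Guides of TCONS_00015940 differed in the target (adjusted p = 9.3e-12), MOB3B (1.2e-15), IFNK (2.1e-15), C9orf72 (1.2e-04) and PLAA (0.00752). Means by guide were 0.07, 13.5 and 0.167 TPM for the target, 0.593, 81.2 and 2.28 for MOB3B, 0.0333, 116 and 0.0167 for IFNK, 4.68, 6.94 and 5.02 for C9orf72 and 24.2, 26.4 and 22.8 for PLAA. At NR_109890 they differed in LINC02202 (2.8e-04), at 6.87, 9.74 and 2.46 TPM, and EBF1 (1.3e-04), at 17.5, 56.3 and 21.3 TPM. At NR_034078 they differed in CASP4LP (1.7e-06), at 18.1, 24.3 and 0.0533 TPM.

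MOB3B differed between the guides of TCONS_00010506 (0.00513), at 0.747, 1.75 and 0.947 TPM against 0.628 in NT. TPST1, a sulfotransferase encoded 2 genes from the target in GRCh38.p14, differed at NR_026873 (6.0e-04), at 33.8, 25.5 and 23.4 TPM against 24.1. ST6GALNAC3, a sialyltransferase encoded 2 genes from its target, differed at NR_125939 (4.1e-04), at 8.79, 6.50 and 5.26 TPM against 6.05. PLAA differed at NR_033834 (0.0362), at 39.3, 35.8 and 35.0 TPM, and at TCONS_00006579 (0.0406), highest with guide 2, both against 36.5 TPM in NT. FZD10, too low to be tested, averaged 0.41 TPM at NR_033834 and was at 0 in NT.

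IFNK, also too low to be tested, reached 1.2 TPM in a TCONS_00026344 library, where the highest NT library had 0.04, and 3 of 7 libraries were above that. An effect of a TCONS_00026344 guide would raise every library of a guide, and 2 guides have libraries on both sides of the highest NT library. Values this near the floor exclude nothing, so that explanation stays open. Reads carried over from the TCONS_00015940 guide 2 libraries would bring IFNK and MOB3B at the ratio of that source. The summed excess had a ratio of 2.38 against 1.43 in the source, at 0.312 and 0.188% of the guide 2 levels, so carried-over reads could be the source. The order of sequencing is not in the labels, and no other test was run.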

How the results depend on the processing

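The split of shared controls, the fits without 2 libraries of NR_109890 or 3 of TCONS_00026344, and the single guides of TCONS_00015940 were chosen only after the result was seen. Where a value below moved, the cause was not tested, except that a limit on the change gives fewer calls by construction. TPM keeps no read depth, so its effect could not be examined.

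A pseudocount of 0.1, no filter and a stricter filter left every count of changed genes within 1.5 times. A change of at least 0.5 on the log2 scale left 1126 genes for MOB3B, 3062 for TCONS_00015940, 507 for NR_109890, 91 for NR_034078, 387 for TCONS_00011252 and 1774 for TCONS_00026344. It left 1173 for TCONS_00010506, 541 for NR_026873, 581 for NR_033834, 929 for NR_125939, 888 for TCONS_00006579 and 988 for TCONS_00009861. Rescaling gave 4564 for TCONS_00015940, 1199 for NR_034078, 3605 for TCONS_00011252 and 5273 for TCONS_00026344. Guide means gave 0 in limma for NR_109890 (2097 at an unadjusted p under 0.05), 3 for NR_034078, 1062 for TCONS_00010506, 1410 for NR_026873, 7 for NR_033834, 636 for NR_125939, 243 for TCONS_00006579 and 1907 for TCONS_00009861. No guide block gave 4951 for NR_033834, 6708 for NR_125939 and 5797 for TCONS_00006579. Without its 2 libraries that stand apart NR_109890 had 2018.

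Leaving out 1 library or 1 guide gave 3989 to 5882 genes for MOB3B, 6420 to 10394 for TCONS_00015940, 130 to 3298 for NR_109890, 148 to 3536 for NR_034078, 3395 to 5693 for TCONS_00011252 and 6998 to 10226 for TCONS_00026344. It gave 2361 to 5883 for TCONS_00010506, 1853 to 5079 for NR_026873, 404 to 4180 for NR_033834, 1646 to 4593 for NR_125939, 739 to 4008 for TCONS_00006579 and 2571 to 5243 for TCONS_00009861. Leaving out an NT guide leaves 1 control guide, assumed to vary like the others.

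The correlation with MOB3B moved at a mean of 5 TPM or more to 0.318 for NR_109890, 0.369 for NR_034078, 0.56 for TCONS_00011252, 0.372 for TCONS_00026344, 0.406 for TCONS_00010506, 0.351 for NR_125939, 0.485 for TCONS_00006579 and 0.208 for TCONS_00009861. Spearman's coefficient was 0.512 for TCONS_00011252 and 0.319 for TCONS_00026344, and guide 3 of TCONS_00015940 alone gave 0.183. With controls split between loci the median r of pairs sharing them went from 0.714 to 0.425.

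Rescaling turned CAAP1 to −0.09 and PLAA to −0.06 at TCONS_00015940, and to −0.01 and −0.07 at TCONS_00026344. Among named genes called on either scale it turned the sign of 18 at TCONS_00015940, 4 of them called on both scales, and of 11 at TCONS_00026344, 2 of them called on both. It turned the interferon (adjusted p = 0.0209), ribosomal (6.2e-19) and oxidative phosphorylation (4.5e-04) lists at TCONS_00015940, and the ribosomal (1.5e-04) and oxidative phosphorylation (0.696) lists at TCONS_00026344. With fry, which does not compare a list with other genes, lists turned in 3 of the 4 tables with a shifted median. At TCONS_00015940 these were MAPK (0.00122), melanocyte (8.0e-04), dedifferentiation (9.6e-06), matrix (0.00111), histone (0.0014) and fibroblast and endothelial (0.0022). At TCONS_00011252 they were Hippo (0.0139), MAPK (0.029), p53 (0.00635) and interferon (0.914). At TCONS_00026344 they were Hippo (3.4e-04), MAPK (0.945), melanocyte (0.0282), dedifferentiation (4.0e-04), p53 (0.00172), matrix (5.5e-04), epithelial (4.9e-04) and fibroblast and endothelial (0.0078). An estimated correlation left 154 of the list results on their side of the threshold and weakened 98.

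With the replicate number as a replicate block 5818 genes changed for MOB3B and 2194 for NR_034078. Residuals of libraries with the same number had a mean r of 0.045 for MOB3B and −0.0186 for NR_034078, against −0.0225 and 0.00923 for other pairs. These values give no sign of pairing at NR_034078. For MOB3B only 3 pairs share a number, too few to decide whether the numbers mark pairs. No paired analysis was possible because the NT replicate numbers are not shared with the libraries of the other 10 loci. Alternatives for read counts gave no value, since the tables hold TPM, and MOB3B has no guides, so the guide alternatives gave none there.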

Other observations

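Some genes past the test were left out above. PHGDH, the first enzyme of serine synthesis, rose at NR_125939 (0.67, SE 0.07, adjusted p = 6.6e-06 by limma) and TCONS_00006579 (0.76, SE 0.06, 2.5e-06). MMP3, a matrix protease, rose on rescaled values at TCONS_00011252 (0.98, SE 0.22, 0.0041) and TCONS_00026344 (0.91, SE 0.08, 3.6e-06). IL24, a cytokine, fell by 1.62 at TCONS_00006579 (SE 0.18, 2.8e-05), and IGFBP3 rose by 0.82 at TCONS_00009861 (SE 0.08, 3.8e-06).

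All tests of explanations below were chosen only after the result was seen, apart from the splits of libraries.

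Higher calls outnumber lower ones in the 4 total RNA tables where TCONS_00022986 holds the largest share of the TPM. Its share fell by 6.88, 4.74, 5.62 and 6.54 points at TCONS_00015940, NR_034078, TCONS_00011252 and TCONS_00026344. A few genes taking most of the counts would raise all others by what they free. The shift expected from the TPM outside the 10 most abundant came within 0.0725 log2 of the median change in each table, but every library has the same total, which largely fixes that, so this explanation stays open. An effect of the activated locus on TCONS_00022986 stays open too. Its share fell by more than 2 SD in 4 of 4 tables, which the contrast with NT libraries alone could also give. Activated and NT libraries of these tables carry the same total RNA label.

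Many genes were higher or lower at most loci. Control libraries shared between tables are not the whole cause, since the lowest correlation over pairs of loci without a shared library was 0.243. Each locus also correlated with MOB3B against GFP, which uses no NT library, at 0.158 or more. No unrelated comparisons were available to set a level for such an r, so a property of the NT libraries alone stays open. A rise of the targeted transcript stays open. The E2F and G2/M list rose at NR_026873 (adjusted p = 1.0e-76 on rescaled values), where LINC00174 was at 0.492 TPM against 0.497, but a transcript this near the floor excludes nothing. A difference between culture batches was not tested.

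Other splits of the libraries were fitted for each locus, 100 per locus with the real one, and 1 of 100, the real one, gave as many changed genes at each of the 11 loci. These splits break up guides, and every other split mixes activated and NT libraries, so the real difference enters its spread. Low counts in the other splits can follow from that. Replicates of 1 guide are also not independent tests of a locus, so the splits do not exclude chance. Real and highest other counts were 9783 and 6 for TCONS_00015940, 916 and 2 for NR_109890, 2657 and 5 for NR_034078, 5614 and 3 for TCONS_00011252, 9748 and 3 for TCONS_00026344 and 4972 and 3 for TCONS_00010506. They were 4195 and 2 for NR_026873, 2375 and 4 for NR_033834, 3988 and 2 for NR_125939, 3414 and 7 for TCONS_00006579 and 4381 and 4 for TCONS_00009861. These fits estimate the guide correlation from 200 genes, so the real counts differ from those above. For MOB3B the 10 splits are too few for a share under 0.05, with 6142 genes in the real one and 4 in the highest other.

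Splits that keep guides whole number 10 per locus, too few for a share under 0.05. The highest other counts were 3600 for TCONS_00015940, 390 for NR_109890, 1017 for NR_034078, 644 for TCONS_00011252, 354 for TCONS_00026344, 1798 for TCONS_00010506, 2150 for NR_026873, 1623 for NR_125939, 1215 for TCONS_00006579 and 2041 for TCONS_00009861, and 1 split, the real one, was as large at each. At NR_033834 2 splits were as large as the real count of 2375: the other, with 2481, sets guide 1 and both NT guides against the rest. At every locus the highest other split groups both NT guides with 1 guide of the locus. It therefore still holds part of the real difference, and its rank does not by itself show a structure of the samples by guide.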
